A study of Homo sapiens with 22 samples.

How the data were processed

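RNA from cultured human acute myeloid leukaemia lines was measured by sequencing of polyadenylated transcripts. The 22 libraries fell into 11 groups of 2, given by line and treatment in the sample titles. MOLM-13, MV-4-11 and THP-1 cells had received dimethyl sulfoxide (DMSO, the solvent) or 1 µM BRM014 for 24 or 72 h. BRM014 inhibits SMARCA4 and SMARCA2, the ATPases of the SWI/SNF chromatin remodelling complexes. THP-1 cells had also received 10 nM phorbol 12-myristate 13-acetate (PMA) for 48 h followed by 24 h without it, or 3 µM DB2313, an inhibitor of the transcription factor PU.1 (gene SPI1), for 72 h. The labels do not say how long each DMSO library had been in culture, so 1 DMSO group served both times of its line. Effects given for BRM014 may thus include effects of time in culture. The labels also do not say whether the DB2313 libraries were made together with the THP-1 DMSO libraries. Nothing in the labels says that the 2 replicates of a group were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

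The deposited values were counts of reads for each gene symbol, 1 library per file, with no normalization by the authors in the files. The submitters' processing notes name HISAT2 2.1.0, HTSeq, DESeq2 and the genome build hg38, without the role of each, the gene annotation or the strand setting. Each file held 28063 gene symbols, of which 25817 occur in GENCODE v29, and 5 summary lines that name no gene. These lines were left out of library sizes and tests. Their no-feature entry held 12.0% to 19.2% of all reads counted in a file (median 15.1%), and their ambiguous entry 3.04% to 3.82%. The strand of counting is not stated, so values of genes that overlap on either strand are uncertain, as are those of genes with near-identical copies. Chromosome positions were taken from GENCODE v29 on GRCh38 by symbol. Transcripts of the mitochondrial genome, chosen as a sign of RNA quality, are not in the files and were not analysed here.

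The reads given to genes numbered 15893489 to 21565666 per library, and 15889 to 18937 genes had at least 1 read. A count of 0 in 1 library allows up to 3 counts at 95% confidence, which is 0.133 to 0.213 CPM (counts scaled to library size) in single libraries. For groups whose libraries were all at 0, a fold is given as a lower bound against 3 counts over the group. For a group with 1 to 3 counts the ratio of CPM is given with its exact 95% interval (Clopper-Pearson, given the sum of both counts). Such floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

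All 22 libraries entered 1 fit in edgeR 4.0.16 (R 4.3.3) with a coefficient for each group. Genes were kept by filterByExpr with the groups and a minimum count of 10, which left 16794. Library sizes were scaled by TMM, and contrasts were tested with the quasi-likelihood F test, with Benjamini-Hochberg adjustment over all genes tested. A gene was called when its adjusted p was under 0.05, and "rose", "fell", "higher" and "lower" in counts of genes refer to calls. Values are log2 fold changes ± standard error (the fold change divided by the square root of F), from 2 libraries in each group, or CPM as mean ± SD (n = 2). The comparisons were BRM014 with DMSO at each time, as the mean of the 3 lines and in each line; 72 h with 24 h of BRM014 in each line; the difference between lines in the BRM014 effect at each time (an F test of both differences); PMA with DMSO, DB2313 with DMSO and BRM014 at 72 h with DB2313 in THP-1 cells.

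Chosen before the data were examined were the groups, the comparisons, the tests, the alternative settings named here, 25 gene lists and the rule for genes named in the text. The lists hold SWI/SNF subunits, blood transcription factors, PU.1 target genes, the KMT2A fusion program, MYC and ribosome biogenesis, DNA replication, mitosis, p53 target genes, the BCL2 family, macrophage markers, granulocyte genes, the inflammatory response, the interferon response, MHC class II, lysosome, cholesterol synthesis, the integrated stress response, unfolded protein and heat shock, ERK and immediate early genes, FLT3 and STAT5 output, adhesion and matrix, erythroid and megakaryocyte genes, lymphoid genes, epithelial and fibroblast genes, and the mitochondrial genome. The erythroid, lymphoid and epithelial lists stand for cells of other types. Of their 21, 15 and 11 members, 6, 11 and 7 were tested, and of 12 MHC class II genes 6 were. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 24 lists with at least 5 tested members within a comparison. An estimated correlation, and fry, which tests whether a list's genes move one way on balance and compares them with no other genes, were alternatives. Counts of called members are over all genes tested; where the count adjusted over the list alone differs, it is given.

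The rule named SMARCA4, SMARCA2 and SPI1, and MYC, MYB, CEBPA, CDKN1A, ITGAM, CD14, CSF1R, HOXA9, MEIS1, FLT3, BCL2 and IRF8, whatever their values. It named the 8 largest rises and 8 largest falls in the mean of the lines at each time among genes called in the same direction in all 3 lines. It named the 10 largest rises and falls for PMA and for DB2313, and the 3 largest in each line and time, among called genes whose treated libraries lay on 1 side of both DMSO libraries. It named the 6 genes with the smallest p for a difference between lines at each time. All of these needed a mean of at least 10 CPM in 1 of the groups compared. From each list and comparison it allowed up to 4 called members in the direction most took and up to 2 in the other, by smallest adjusted p, and any member of a list with under 5 called. Genes of the Y chromosome and XIST were left out.

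Similarity of effects was measured by Pearson correlation and covariance of log2 fold changes across genes, which are not independent replicates, so no p is given, and by overlap of calls beside the number that independent choices would share. Comparisons that share a DMSO group were set beside 20 simulations of unchanged groups. Alternative settings were RLE size factors, library size only, DESeq2 1.42.0 (Wald test, or its likelihood ratio test for line differences), no count filter, a filter of 1 CPM in 2 libraries, smaller sets of libraries in the fit, a 2-fold minimum, the replicate number as a block, and leaving out each library in turn, which assumes that the lone library of a group varies like those of the other groups. The replicate numbers were checked for pairing between groups of a line. The correlations of replicate differences lay between -0.117 and 0.0852, so no strong pairing was seen. A weak pairing is not excluded, since counting error lowers such correlations. The fit was tested on simulated data with known changes: in the mean of the lines at 24 h it found 74.6%, 83.6% and 93.9% of genes changed by 1.5-fold, 2-fold and 4-fold, in MOLM-13 at 72 h 53.7%, 74.6% and 84.8%, for PMA 59.7%, 74.6% and 95.5%, for DB2313 58.2%, 79.1% and 97.0%, and for line differences at 24 h 29.9%, 70.1% and 86.4%. Among unchanged simulated genes it called 10, 12, 7, 4 and 6. The simulations changed 66 or 67 genes by each fold and drew counts from the fitted spread. They do not test the scaling where a large share of genes change, as in these data.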

Results

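The series comprised 22 RNA-seq libraries of 3 acute myeloid leukaemia cell lines with KMT2A fusions, MOLM-13, MV-4-11 and THP-1, in 11 groups of 2. Each line had a DMSO group and groups treated with BRM014, an inhibitor of the SWI/SNF ATPases SMARCA4 and SMARCA2, for 24 h and 72 h. THP-1 had further groups treated with PMA, a phorbol ester that drives monocytic cells towards macrophages, and with DB2313, an inhibitor of PU.1. The libraries held 15893489 to 21565666 reads in genes. Replicates correlated at r = 0.989 to 0.997 across genes on the log2 CPM scale. Their counts varied beyond counting error in every pair, with a chi-square per degree of freedom of 32.7 for the PMA pair, 11.4 for DB2313, 9.77 for MOLM-13 DMSO and 3.23 to 7.13 for the other groups. The share of reads outside annotated genes differed between some groups. It was 13.2% and 12.4% in the MOLM-13 DMSO libraries, 13.0% and 13.6% after 24 h and 18.2% and 18.4% after 72 h of BRM014. In MV-4-11 it was 14.3% and 13.8% with DMSO, under these values in both libraries at 24 h, and 13.1% and 13.5% at 72 h. In THP-1 it was 16.5% and 15.8% with DMSO, 18.4% to 19.2% with BRM014, 17.9% and 18.7% with DB2313, and 16.0% and 12.4% in the PMA libraries.

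Transcripts of the drug targets were present in every group. SMARCA4 (chromosome 19, 10960825 to 11079426, plus strand) was at -0.04 ± 0.04 in the mean of the lines at 24 h (adjusted p = 0.367), with a log2 fold change of 0.037 and no call when library size alone was the scaling, and fell (-0.49 ± 0.04) at 72 h. SMARCA2 (chromosome 9, 1980290 to 2193624, plus strand) fell in the mean of the lines (-0.20 ± 0.03 and -0.39 ± 0.03). Its effect differed between lines (F test adjusted p = 6.6e-05 at 24 h and 1.3e-06 at 72 h). In MOLM-13 at 72 h the sign of its change depended on the setting. SPI1 (chromosome 11, 47354860 to 47378576, minus strand), which encodes PU.1, fell at both times. In THP-1 it went from 307 ± 11.1 CPM with DMSO to 86.8 ± 2.32 at 24 h and 51.0 ± 1.81 at 72 h. In MOLM-13 it went from 336 ± 55.5 to 133 ± 16.8 and 184 ± 0.537, and in MV-4-11 from 337 ± 5.68 to 84.6 ± 1.55 and 182 ± 9.53. MYC (chromosome 8, 127735434 to 127741434, plus strand), a transcription factor that drives growth, was at -3.45 ± 0.05 at 24 h and -5.04 ± 0.05 at 72 h. Its level in MOLM-13 went from 776 ± 45.9 to 71.6 ± 2.17 and then 9.11 ± 0.793 CPM.

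**Figure D1:**
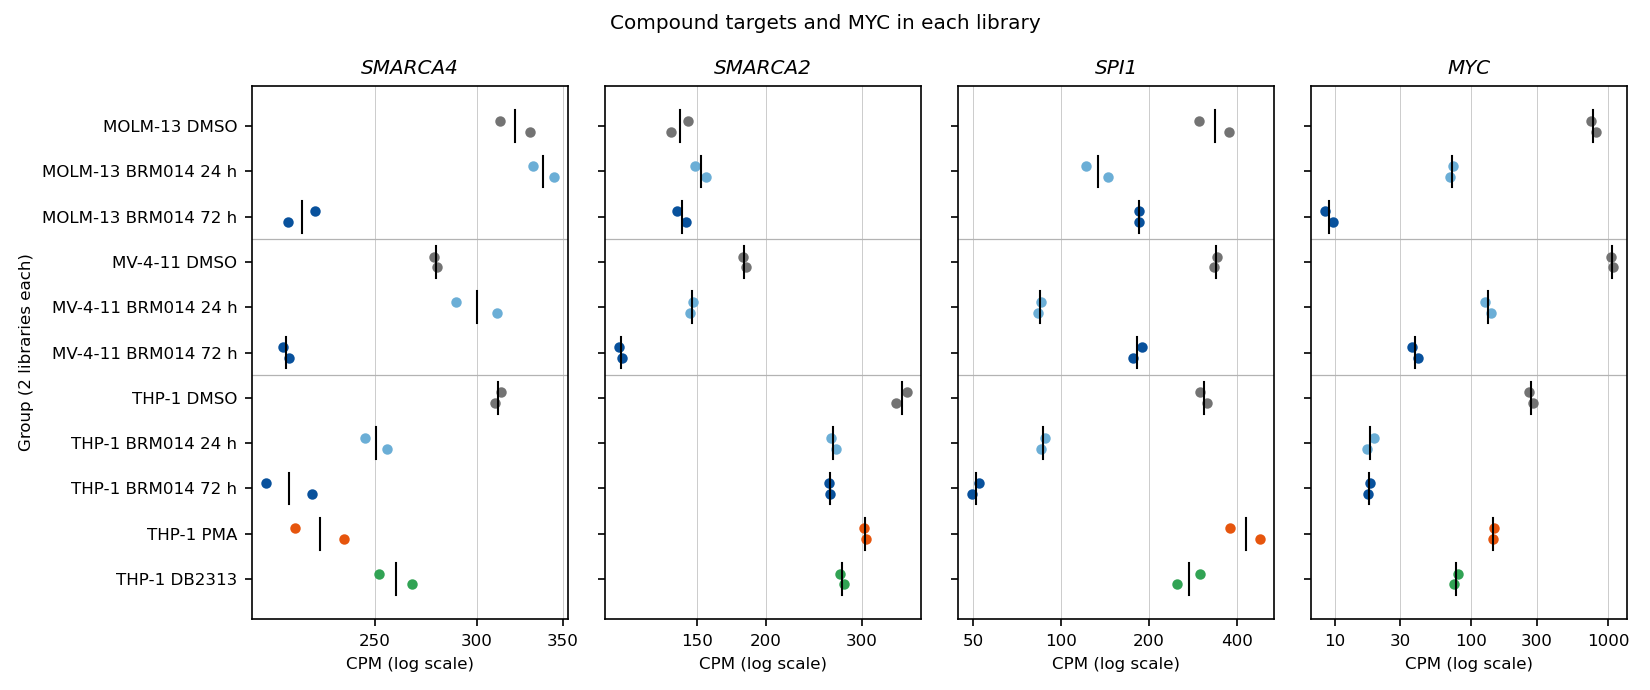
Expression of SMARCA4, SMARCA2, SPI1 and MYC in CPM (log axis) in each of the 11 groups, where points are libraries and lines are means of 2. SPI1 in THP-1 lay at 307 CPM with DMSO, 51.0 after 72 h of BRM014 and 273 with DB2313, and MYC lay at 273, 17.9 and 77.4.

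Comparison of BRM014 with DMSO at 24 h asked which transcripts follow SWI/SNF activity early. The largest falls shared by all 3 lines included SASH3, a signalling adapter of blood cells (-5.81 ± 0.11), the integrin ITGAX (-4.08 ± 0.14), and HAL, a histidine-degrading enzyme (-4.40 ± 0.10). CCDC26, a long non-coding RNA on the MYC arm of chromosome 8 (chromosome 8, 128634199 to 129683679, minus strand), fell (-6.50 ± 0.23), and TMC8 (-4.49 ± 0.09). DCANP1 (-7.33 ± 0.24), MS4A14 (-6.33 ± 0.28) and MS4A7 (-5.19 ± 0.10) also fell. DCANP1 overlaps TIFAB, and MS4A7 overlaps MS4A14, on the same strand, so their separate values are uncertain. The largest rise was that of CTTN (chromosome 11, 70398404 to 70436584, plus strand), which encodes the actin-binding protein cortactin, at 7.17 ± 0.10, and DMPK, a kinase gene of muscle, rose by 4.95 ± 0.18. Further rises were in HMOX1, which encodes the haem-degrading heme oxygenase (4.32 ± 0.16), DMWD (4.05 ± 0.09), and MAP1A, a microtubule protein (3.68 ± 0.22). So did the transcription factors KLF2 (3.63 ± 0.10) and PPARG (3.48 ± 0.06) and DNASE2, a lysosomal nuclease (3.47 ± 0.08). The largest adjusted p among these 16 genes was 9.6e-12 (edgeR quasi-likelihood, Benjamini-Hochberg).

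Genes of growth and sterol synthesis fell at 24 h in the mean of the lines. All 30 of 30 genes of MYC and ribosome biogenesis fell (camera adjusted p = 3.8e-17), among them NOLC1, a nucleolar protein (-1.48 ± 0.04), and the glycolytic enzyme LDHA (-1.38 ± 0.05). All 19 cholesterol synthesis genes fell (6.3e-12), among them HMGCS1, an early enzyme of the pathway (-1.54 ± 0.05), INSIG1, which restrains it (-1.70 ± 0.04), and CYP51A1 (-1.64 ± 0.04). Of 35 PU.1 target genes, 22 fell and 5 rose (3.8e-06). The kinase BTK was at -2.58 ± 0.05, the granule enzyme MPO at -2.79 ± 0.11 and the protease CTSS at -2.17 ± 0.06. Of 25 DNA replication genes, 18 fell and 3 rose (0.00154; adjusted p = 0.245 with an estimated correlation), with the helicase subunits MCM2 at -0.82 ± 0.05 and MCM3 at -0.82 ± 0.04. Granulocyte genes fell in 10 and rose in 4 of 19 (0.0102; adjusted p = 0.245 with an estimated correlation), with the bactericidal enzyme LYZ at -1.79 ± 0.04 and the growth factor receptor CSF3R at -1.53 ± 0.04.

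Lysosomal, p53 and immediate early genes rose on balance at 24 h in the mean of the lines. Lysosomal genes rose in 16 and fell in 4 of 24 (camera adjusted p = 0.00341; adjusted p = 0.245 with an estimated correlation), with GRN (1.22 ± 0.04), the sphingolipid activator PSAP (1.17 ± 0.04) and the autophagy receptor SQSTM1 (1.30 ± 0.04) higher. Targets of p53 rose in 14 and fell in 7 of 22 (0.0231; adjusted p = 0.236 with an estimated correlation), with TP53INP1 at 2.28 ± 0.09 and the cell cycle inhibitor CDKN1A at 1.94 ± 0.05. ERK and immediate early genes rose in 13 and fell in 3 of 19 (0.00164; adjusted p = 0.206 with an estimated correlation), EGR1 by 2.89 ± 0.10. In MOLM-13 alone, p53 targets were 10 higher and 9 lower of 22, and ERK genes 6 and 5 of 19. Targets of p53 were 13 and 4 in both MV-4-11 and THP-1, and ERK genes 11 and 3, and 12 and 2. The p53 list differed between MOLM-13 and THP-1 (camera adjusted p = 1.1e-09, 0.00398 with an estimated correlation) and between MOLM-13 and MV-4-11 (6.7e-05, 0.0258). The remaining lists had no call in the mean of the lines. SWI/SNF subunits were 14 higher and 6 lower of 27 (adjusted p = 0.0642, and called with library size alone at 0.0442; BICRAL 1.24 ± 0.06, SMARCC1 -0.50 ± 0.04). Blood transcription factors numbered 12 and 10 of 28 (0.733; RUNX1 1.11 ± 0.04, MEF2D -1.69 ± 0.04), genes of the KMT2A fusion program 8 and 7 of 22 (0.631) and of mitosis 6 and 6 of 20 (0.822; 6 and 7 adjusted over the list alone). Mitosis genes were 1 higher and 13 lower in MOLM-13 (2 and 14 adjusted over the list alone). They were 8 and 1 in MV-4-11 and 4 and 1 in THP-1. MOLM-13 differed from MV-4-11 in this list (camera adjusted p = 2.6e-07, 0.0215 with an estimated correlation). In the same order the KMT2A program had 2 and 13, 7 and 3 (8 and 4 adjusted over the list alone), and 7 and 8. MOLM-13 and MV-4-11 differed here too (3.8e-04, 0.0493). The apoptosis regulators of the BCL2 family were higher in 5 and lower in 6 of 15 (0.903; 5 and 7 adjusted over the list alone), with MCL1 at 1.43 ± 0.04 and BCL2 at -1.18 ± 0.04. Macrophage markers were higher in 7 and lower in 9 of 30 (0.553; 7 and 10 adjusted over the list alone).

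The count of interferon response genes at 24 h was 4 higher and 13 lower of 27 (camera adjusted p = 0.112), of inflammatory genes 8 and 5 of 22 (0.553), and of the integrated stress response 5 and 11 of 18 (0.0770; the serine enzyme PSAT1 -1.40 ± 0.05). Genes of unfolded protein and heat shock were higher in 5 and lower in 8 of 16 (0.640; 6 and 8 adjusted over the list alone; XBP1 2.26 ± 0.05). FLT3 and STAT5 output was higher and lower in 6 and 5 of 14 (0.814; the cytokine OSM 3.24 ± 0.10), and adhesion and matrix genes in 6 and 6 of 20 (0.822; CD44 -2.15 ± 0.07). MHC class II genes were lower in 3 of 6 tested (0.147; CD74 -1.51 ± 0.05). Markers of other cell types gave no list call: erythroid and megakaryocyte genes 3 higher and 1 lower of 6 (0.702), lymphoid 1 and 4 of 11 (0.198), epithelial and fibroblast 1 and 1 of 7 (0.822). Among single genes, IRF8, a transcription factor of monocytes (chromosome 16, 85898803 to 85922609, plus strand), fell (-2.95 ± 0.05), and CSF1R, the receptor for macrophage growth factor (chromosome 5, 150053291 to 150113372, minus strand), fell (-4.62 ± 0.15). HOXA9 rose by 0.56 ± 0.11, CD14 (chromosome 5, 140631728 to 140633701, minus strand) by 1.73 ± 0.45 and CEBPA, a myeloid transcription factor, by 0.36 ± 0.06. In that order, their effects differed between lines with F test adjusted p of 0.0011, 7.4e-05 and 2.6e-05. The sign of HOXA9 in MOLM-13 and of CD14 in MV-4-11 depended on the libraries kept. MYB was at -0.06 ± 0.04 (adjusted p = 0.226). Its log2 fold change was 0.021, without a call, with library size alone, and -0.08 (adjusted p = 0.0225) without the PMA and DB2313 libraries. The call of CD14 ended without replicate 1 of MOLM-13 at 24 h (1.46, adjusted p = 0.0689). Leaving out 1 library moved further folds by over 1.5 times: CD14 to 2.60 without replicate 2 of MOLM-13 DMSO, CTTN to 7.81 without replicate 2 of MV-4-11 DMSO, and DMPK to 5.61 and MAP1A to 4.54 without replicate 2 of THP-1 DMSO. It moved DCANP1 to -8.07 and MS4A14 to -7.46 without replicate 1 of 24 h BRM014 in MV-4-11 and in MOLM-13. Altogether 4859 genes rose and 4544 fell of 16794 tested, 1532 and 1593 of them in all 3 lines (233 and 213 if the lines were independent).

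At 72 h the same comparison showed larger changes. CTTN rose by 7.60 ± 0.10, HP, the plasma protein haptoglobin, by 7.45 ± 0.17, and PTGDS, a prostaglandin D synthase, by 6.98 ± 0.15. HP has the near-identical copy HPR, so its value is uncertain. Other large rises were those of SYNPO, an actin-associated protein (5.84 ± 0.12), DMPK (5.75 ± 0.17), HMOX1 (5.50 ± 0.15), complement C3 (5.04 ± 0.06) and DNASE2 (5.02 ± 0.08). CCDC26 fell (-8.75 ± 0.29), SASH3 (-7.54 ± 0.13), MS4A14 (-7.57 ± 0.33), MS4A7 (-6.30 ± 0.12) and ITGAX (-6.09 ± 0.20). LY86, which partners a Toll-like receptor relative, fell (-5.58 ± 0.28) and ARMH1 (-5.51 ± 0.12). DCANP1 had 1 count in all BRM014 libraries at 72 h against 2305 with DMSO, a ratio of 4.0e-04, 95% counting interval 1.0e-05 to 0.00221. The survival factor BCL2 fell (-3.11 ± 0.04), IRF8 (-3.82 ± 0.06) and CSF1R (-4.84 ± 0.16). CD14 rose by 3.34 ± 0.37 and CDKN1A (chromosome 6, 36676460 to 36687339, plus strand) by 2.14 ± 0.05. MYB fell (-0.53 ± 0.04), and CEBPA (0.71 ± 0.06) and HOXA9 (0.39 ± 0.11) rose. The effects of CD14, MYB, CEBPA and HOXA9 differed between lines (F test adjusted p of at most 0.0143). The sign of HOXA9 in MOLM-13 and of CEBPA in THP-1 depended on the libraries kept. Leaving out 1 library moved CTTN to 8.24 (MV-4-11 DMSO replicate 2), DMPK to 6.41 (THP-1 DMSO replicate 2), and CD14 to 4.21 (MOLM-13 DMSO replicate 2). Among falls it moved CSF1R to -6.08 (replicate 1 of 72 h BRM014 in MV-4-11), CCDC26 to -9.53 (the same library) and -9.55 (replicate 2 of 72 h BRM014 in THP-1), and LY86 to -7.36 and -6.28 (replicate 2 of 72 h BRM014 in MV-4-11 and in THP-1), with DCANP1 at -11.53 without the former. Altogether 5854 genes rose and 5108 fell at 72 h, 2275 and 2432 of them in all 3 lines (446 and 361 if independent).

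Mitosis and DNA replication genes fell in the mean of the lines at 72 h. All 20 mitosis genes fell (camera adjusted p = 6.3e-10), with the kinase PLK1 at -1.48 ± 0.04 and cyclin CCNA2 at -1.19 ± 0.04, as did 24 of 25 DNA replication genes (1.1e-12; MCM2 -1.92 ± 0.05). MYC and ribosome biogenesis genes fell in 30 of 30 (4.4e-17; DKC1 -1.87 ± 0.04), and cholesterol synthesis genes in 19 of 19 (5.4e-09; FDFT1 -1.65 ± 0.04, SQLE -1.43 ± 0.04). Lysosomal genes rose in 22 and fell in 1 of 24 (3.6e-09), with SQSTM1 at 3.01 ± 0.05, CTSD, a lysosomal protease, at 2.61 ± 0.05 and GRN at 2.60 ± 0.04. PU.1 target genes fell in 21 and rose in 10 of 35 (0.00106; adjusted p = 0.0871 with an estimated correlation), with BTK at -3.16 ± 0.05 and the scavenger receptor CD68 at 1.91 ± 0.04. ERK and immediate early genes rose in 12 and fell in 5 (0.0366; adjusted p = 0.358 with an estimated correlation). In MOLM-13 and THP-1 the lysosomal and cell cycle changes at 72 h went with the higher share of reads outside genes given above. In MV-4-11 the share at 72 h was 13.1% and 13.5%, under the 14.3% and 13.8% with DMSO. Lysosomal genes there were 21 higher and 2 lower, and DNA replication genes 2 and 22. Mitosis genes fell in 19 (20 adjusted over the list alone). In that line these values argue against a higher share as the source. In THP-1 the share was already 18.4% and 18.9% at 24 h. Lysosomal genes were then 12 higher and 4 lower, DNA replication genes 0 and 22, and mitosis genes 4 and 1.

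The remaining lists were not called at 72 h. Members higher and lower numbered 14 and 8 of 27 for SWI/SNF subunits (camera adjusted p = 0.680; 14 and 9 adjusted over the list alone), 10 and 13 for blood transcription factors (0.372), 4 and 9 for the KMT2A fusion program (0.0643). The counts were 15 and 7 for p53 targets (0.132; TP53I3 4.17 ± 0.11) and 5 and 7 for the BCL2 family (0.696). They numbered 10 and 10 for macrophage markers (0.850), 7 and 6 for granulocyte genes (0.881; lower in the test with library size alone, 0.919) and 11 and 3 for inflammatory genes (0.0615). Interferon genes had 11 higher and 11 lower (0.850), and MHC class II 0 and 3 (0.0615, and called with library size alone at 0.0415; CD74 -3.67 ± 0.06). The integrated stress response had 5 higher and 9 lower (0.205; PHGDH -2.29 ± 0.06), unfolded protein and heat shock genes 6 and 9 (0.176; HSPD1 -2.43 ± 0.04) and FLT3 and STAT5 output 7 and 3 (0.536). Adhesion and matrix genes had 9 and 4 (0.536), erythroid and megakaryocyte 4 and 1 (0.330), lymphoid 1 and 5 (0.205), and epithelial and fibroblast 2 and 1 (0.372). In the means of the lines, the list calls that held with an estimated correlation were MYC and ribosome biogenesis (adjusted p = 0.0123 at 24 h and 0.00829 at 72 h) and cholesterol synthesis (1.9e-04 and 9.0e-04) at both times. PU.1 target genes held at 24 h (0.0286), and DNA replication (0.0186), mitosis (0.00829) and lysosome (0.0186) at 72 h. Median, mean and test differed in sign only for lists without a call. These were at 24 h the BCL2 family, inflammatory, FLT3 and STAT5, and erythroid lists, and at 72 h the interferon, FLT3 and STAT5, and adhesion lists.

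**Figure D2:**
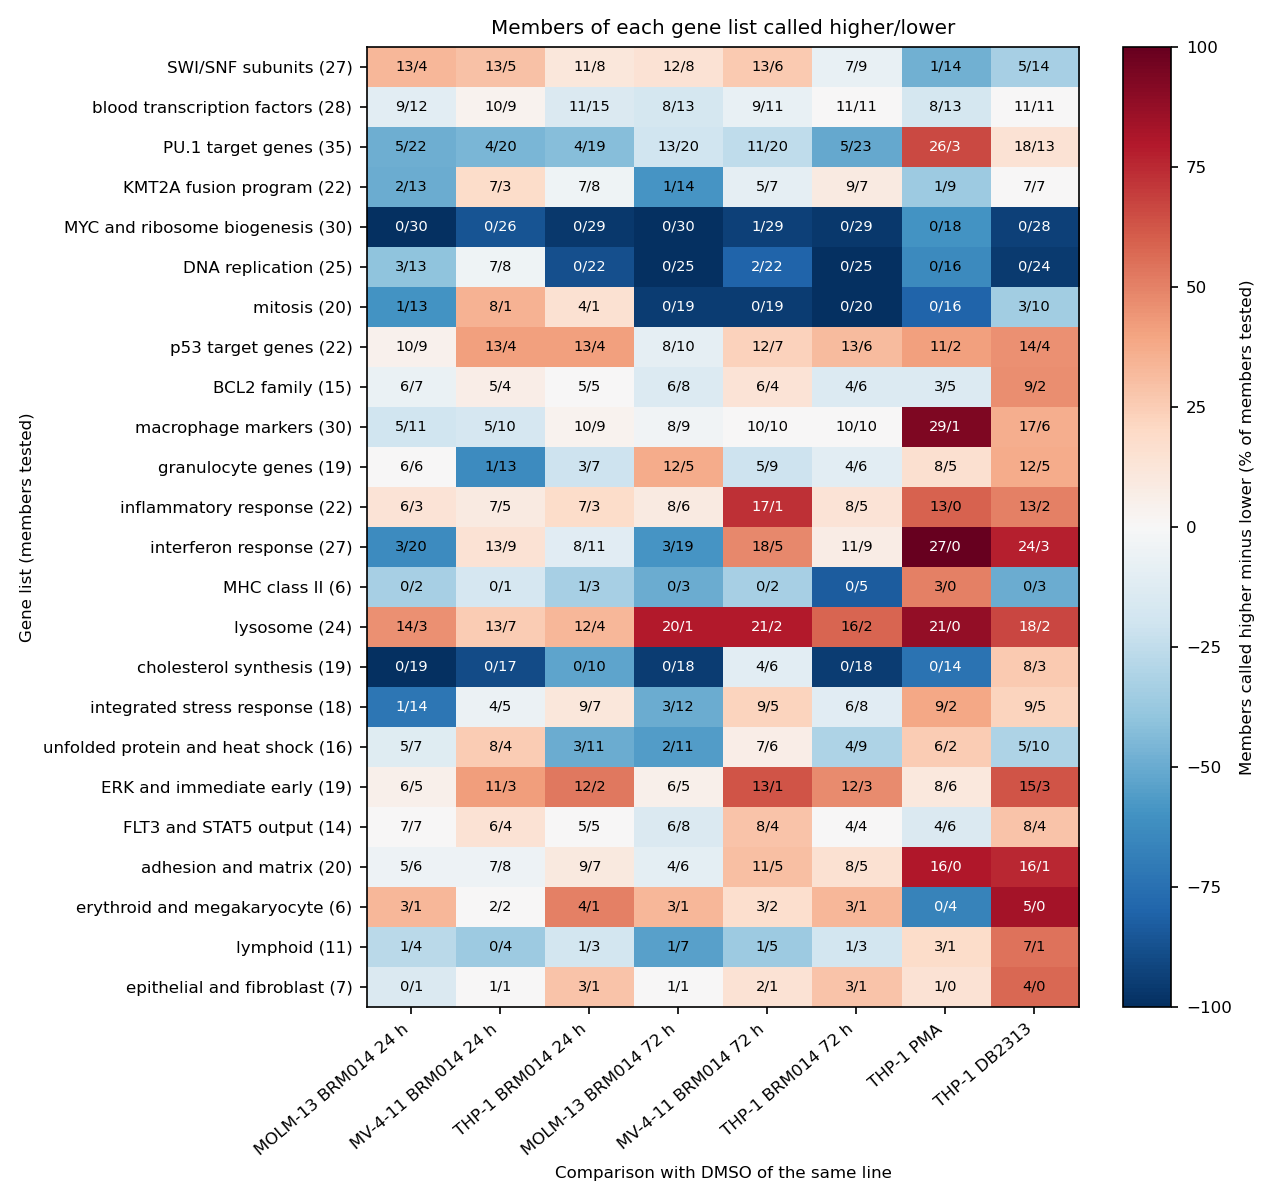
Members of each of 24 gene lists called higher minus members called lower, as a percentage of tested members (colour), in 8 comparisons with DMSO; the numbers in the cells are members higher and lower. Cholesterol synthesis had 0 higher and 19 lower of 19 in MOLM-13 at 24 h and 4 higher and 6 lower in MV-4-11 at 72 h, and the interferon response had 27 higher and 0 lower of 27 with PMA.

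In each line apart, the question was which changes the mean of the lines does not show. In MOLM-13 at 24 h, LINC00968 rose by 6.79 ± 0.18 and HP by 5.33 ± 0.25. MAFA, a transcription factor of the pancreas, had 420 counts against 3, a ratio of 129, 95% counting interval 43.9 to 628. MYBPH had 1 count against 1208 (ratio 7.6e-04, 95% counting interval 1.9e-05 to 0.00426) and the cytokine IL32 1 against 361 (ratio 0.00255, 95% counting interval 6.4e-05 to 0.0143), and TIFAB was at least 129.8-fold lower. At 72 h PTGDS rose by 8.73 ± 0.26, HP by 8.42 ± 0.24 and LINC00968 by 7.94 ± 0.18. ITGAX, DCANP1 and MS4A4A, without a count in the BRM014 group, were at least 542-fold, 255-fold and 153-fold lower. In MV-4-11 CTTN rose by 8.60 ± 0.20 at 24 h and 9.20 ± 0.20 at 72 h. There DMPK rose by 6.12 ± 0.38 and DNASE2 by 5.05 ± 0.16 at 24 h, and PTGDS by 8.91 ± 0.29 at 72 h, when LCNL1, its neighbour, was at least 153-fold higher. In the same line FAM135B fell (-7.53 ± 0.49) and C6orf223 (-7.39 ± 0.37) at 24 h, and DCANP1 had 1 count against 434 (ratio 0.00215, 95% counting interval 5.4e-05 to 0.0121). At 72 h CEACAM6, a granulocyte adhesion gene, fell (-9.32 ± 0.26), MS4A14 was at least 153-fold lower, and the calcium channel gene CACNA2D3 had 1 count against 647 (ratio 0.00158, 95% counting interval 4.0e-05 to 0.00885). In THP-1 CTTN rose by 7.83 ± 0.18 and 8.07 ± 0.17, EGR3 by 6.54 ± 0.34 and LINC00968 by 6.46 ± 0.16 at 24 h. In that line at 24 h MPEG1, a pore-forming protein of macrophages, had 1 count against 518 (ratio 0.00166, 95% counting interval 4.2e-05 to 0.00929), CCDC26 2 against 786 (ratio 0.00219, 95% counting interval 2.6e-04 to 0.00793) and GPA33 1 against 430 (ratio 0.00200, 95% counting interval 5.1e-05 to 0.0112). At 72 h CDH1 (E-cadherin) was at least 376-fold higher, a call lost in DESeq2 (adjusted p = 0.150), and ANGPTL4, a regulator of lipoprotein lipase, had 614 counts against 3 (ratio 203, 95% counting interval 69.1 to 986). DCANP1, GPA33 and CEBPE, a granulocyte transcription factor, were at least 440.0-fold, 145-fold and 129-fold lower in THP-1 at 72 h. Leaving out 1 DMSO library in turn moved CTTN in MV-4-11 to 7.88 and 10.53 at 24 h and 8.48 and 11.14 at 72 h, and PTGDS to 7.97 and 10.18 in MOLM-13 and 9.95 and 8.23 in MV-4-11. It moved EGR3 in THP-1 to 7.46 and 5.90, and without replicate 1 DMPK in MV-4-11 to 6.93 at 24 h and LINC00968 in MOLM-13 to 7.38 at 24 h. Leaving out replicate 1 or 2 of 72 h BRM014 moved CEACAM6 to -10.37 and -8.67. Fitted folds of genes with 1 to 3 counts in a group rest on few reads: without replicate 1 or 2 of that group MAFA was at 5.90 and 10.96, MYBPH at -12.60 and -9.20, IL32 at -7.49 and -10.86, MPEG1 at -11.07 and -7.95, GPA33 in THP-1 at 24 h at -10.80 and -7.68, DCANP1 in MV-4-11 at 24 h at -10.72 and -7.58 and CACNA2D3 at -11.30 and -8.06, and ANGPTL4 was at 8.22 without replicate 1 of DMSO. Genes higher and lower numbered 3808 and 3952 in MOLM-13, 3971 and 3763 in MV-4-11 and 4345 and 4045 in THP-1 at 24 h, and 5083 and 4942, 4771 and 4382, and 5188 and 4698 at 72 h. With library size alone as the scaling, the share of MOLM-13 calls at 24 h that were higher went from 49.1% to 59.3%. The median of all genes moved by 0.126 there, 0.191 in MOLM-13 at 72 h and 0.112 in the mean of the lines at 72 h, so directions of small changes are relative to the scaling.

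The BRM014 effect differed between the lines for 7300 genes at 24 h (43.5% of those tested) and 8881 at 72 h (52.9%). THBD, which encodes the anticoagulant receptor thrombomodulin, rose by 1.86 ± 0.10 in MOLM-13 and 3.92 ± 0.10 in MV-4-11 at 24 h and fell (-0.45 ± 0.08) in THP-1. LRG1 rose by 1.31 ± 0.10 in MOLM-13 and 2.17 ± 0.10 in THP-1 and fell (-2.32 ± 0.12) in MV-4-11. S1PR3, a sphingosine phosphate receptor, rose by 1.99 ± 0.11 in MOLM-13 and 2.59 ± 0.11 in MV-4-11 and fell (-1.85 ± 0.13) in THP-1. SCD, which desaturates fatty acids, fell (-3.46 ± 0.08, -1.95 ± 0.07 and -0.52 ± 0.07) in MOLM-13, MV-4-11 and THP-1 at 24 h. At 72 h it fell (-3.85 ± 0.08 and -1.28 ± 0.07) in MOLM-13 and THP-1 and rose by 0.60 ± 0.07 in MV-4-11. INSIG1 (chromosome 7, 155297776 to 155310235, plus strand) was at -4.53 ± 0.08 in MOLM-13 and -2.56 ± 0.08 in THP-1 at 72 h and was at -0.05 ± 0.07 in MV-4-11 (adjusted p = 0.594), with a log2 fold change of 0.010 and no call with library size alone. FADS2, another desaturase, fell (-5.88 ± 0.13 and -3.56 ± 0.13) and was at 0.10 ± 0.10 in MV-4-11 (adjusted p = 0.430). CDKN1A rose by 2.83 ± 0.09 in MV-4-11 and 4.05 ± 0.09 in THP-1 at 72 h and fell (-0.47 ± 0.08) in MOLM-13. LYZ (chromosome 12, 69348341 to 69354234, plus strand) was at -4.38 ± 0.08 in THP-1 and -0.40 ± 0.07 in MV-4-11 and rose by 0.74 ± 0.07 in MOLM-13. RGS16, a brake on G protein signalling, rose by 3.63 ± 0.12 in THP-1 and 1.16 ± 0.11 in MV-4-11 and fell (-4.48 ± 0.13) in MOLM-13. All of these differences had an adjusted p of at most 7.5e-13 at 24 h or 2.0e-15 at 72 h (F test, edgeR).

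FLT3, MYB and ITGAM, named in advance, also differed between lines. FLT3, a receptor kinase, fell (-0.30 ± 0.06) in MOLM-13 and rose by 0.77 ± 0.06 in MV-4-11 and 0.27 ± 0.06 in THP-1 at 24 h (adjusted p of the difference = 3.7e-08). MYB fell (-0.57 ± 0.07) in THP-1, rose by 0.31 ± 0.07 in MOLM-13 and was at 0.08 ± 0.07 in MV-4-11 (adjusted p = 0.387; difference 1.4e-06). The integrin ITGAM rose by 1.52 ± 0.09 in THP-1 at 24 h and was at -0.46 ± 0.10 in MOLM-13 and -1.24 ± 0.24 in MV-4-11 (difference 9.9e-10). MEIS1, a partner of HOXA9, was at -1.18 ± 0.15 in MOLM-13 and -1.16 ± 0.16 in MV-4-11 at 72 h, while THP-1 had 0 and 5 counts of it with BRM014 and DMSO, and its effect was not called different between the lines (adjusted p = 0.246). Across genes, log2 fold changes of MOLM-13 and MV-4-11 correlated at r = 0.423, MOLM-13 and THP-1 at 0.391 and MV-4-11 and THP-1 at 0.327 (0.534 among genes with an average log2 CPM of at least 3) at 24 h, and at 0.483, 0.494 and 0.434 at 72 h. At 72 h, 3111 genes rose in both MOLM-13 and MV-4-11 (1444 if independent), and 758 were called in opposite directions (2730 if independent). Called genes opposite between any 2 lines numbered 1365 at 24 h and 1561 at 72 h.

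Sterol and interferon genes were among those whose lists differed between the lines. Cholesterol synthesis genes fell in 19 of 19 in MOLM-13 at 24 h, 17 in MV-4-11 (18 adjusted over the list alone) and 10 in THP-1. At 72 h they fell in 18, 6 and 18, with 4 higher in MV-4-11 (5 adjusted over the list alone). The difference between MOLM-13 and MV-4-11 at 72 h had a camera adjusted p of 2.5e-19 (1.5e-05 with an estimated correlation), and all 19 members differed between lines. Interferon response genes fell in 19 and rose in 3 of 27 in MOLM-13 at 72 h (camera adjusted p = 6.5e-05; adjusted p = 0.135 with an estimated correlation). In MV-4-11 18 rose and 5 fell (3.4e-04; adjusted p = 0.194 with an estimated correlation). The difference had an adjusted p of 3.2e-13 (0.0140 with an estimated correlation). IFIT3, an antiviral protein, was at -3.72 ± 0.18 in MOLM-13 and 3.26 ± 0.21 in MV-4-11. The ubiquitin-like ligase HERC5 fell (-3.01 ± 0.16) in MOLM-13 and the transcription factor IRF9 rose in both lines (0.90 ± 0.12 and 2.42 ± 0.12). Inflammatory genes rose in 17 and fell in 1 of 22 in MV-4-11 at 72 h (9.3e-04; adjusted p = 0.337 with an estimated correlation). Integrated stress response genes fell in 14 and rose in 1 of 18 in MOLM-13 at 24 h (3.8e-06; adjusted p = 0.0520 with an estimated correlation; 2 higher adjusted over the list alone). Targets of p53 rose in 13 and fell in 4 of 22 in THP-1 at 24 h (4.8e-05; adjusted p = 0.0376 with an estimated correlation).

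**Figure D3:**
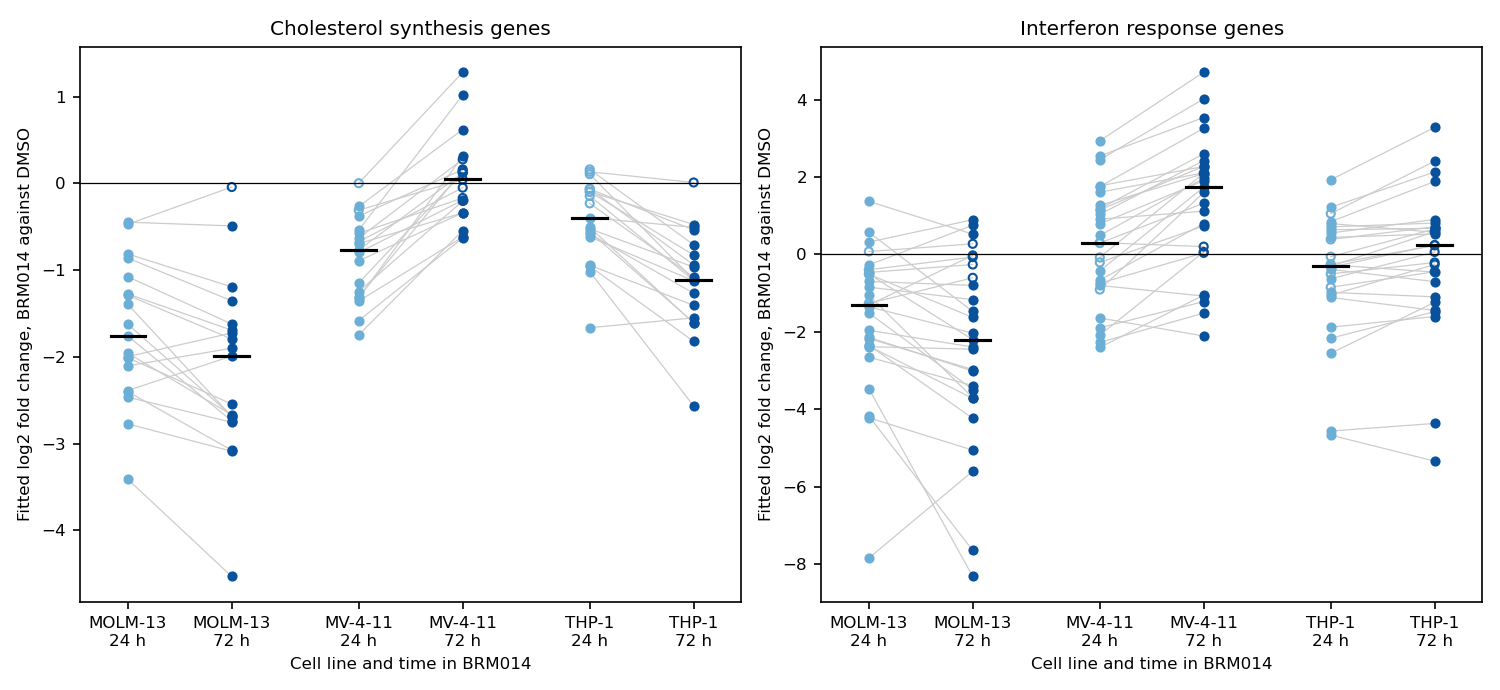
Fitted log2 fold changes with BRM014 against DMSO of cholesterol synthesis and interferon response genes in each line at 24 and 72 h, where filled points are called, open points are not, black bars are medians and grey lines join a gene. At 72 h INSIG1 was at -4.53 in MOLM-13, -0.05 in MV-4-11 and -2.56 in THP-1, and IFIT3 was at -3.72 in MOLM-13 and 3.26 in MV-4-11.

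Changes from 24 h to 72 h of BRM014 may include effects of time in culture, as the labels give no time for DMSO. Between these times the cholesterol genes moved in opposite directions in the lines. All 19 rose in MV-4-11 (camera adjusted p = 7.4e-15, 7.3e-05 with an estimated correlation). STARD4, a sterol carrier, rose by 1.63 ± 0.12 and the reductase DHCR7 by 1.20 ± 0.08. Of the list 14 fell and 2 rose in MOLM-13 (3 adjusted over the list alone) and 16 fell in THP-1. Between these times DNA replication genes fell in 25, 25 and 24 of 25 in MOLM-13, MV-4-11 and THP-1 (25 adjusted over the list alone in THP-1), and mitosis genes in 17, 20 and 20 of 20. Lysosomal genes rose in 20, 21 and 14 of 24 (16 adjusted over the list alone in THP-1), and 1, 0 and 1 fell. SPI1 rose by 0.47 ± 0.12 in MOLM-13, a call that ended without replicate 1 of its 24 h group (0.34, adjusted p = 0.0598), and by 1.11 ± 0.12 in MV-4-11, and fell (-0.77 ± 0.12) in THP-1. PU.1 target genes fell in 18 and rose in 5 of 35 in THP-1 (19 lower adjusted over the list alone; camera adjusted p = 6.2e-05, 0.0432 with an estimated correlation). Interferon genes rose in 21 and fell in 1 of 27 in MV-4-11 (2.5e-07, 0.0361 with an estimated correlation). Genes higher and lower at 72 h than at 24 h numbered 3488 and 3818 in MOLM-13, 3119 and 2830 in MV-4-11 and 2724 and 2766 in THP-1, where 1750 were higher without replicate 1 of the 24 h group. Effects at 24 h and 72 h correlated at r = 0.751, 0.748 and 0.816 across genes, against 0.546, 0.501 and 0.515 in simulations of unchanged groups with the shared DMSO libraries. Their covariance exceeded the simulated one by 1.75, 1.37 and 1.68, and part of each correlation may come from the shared controls.

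PMA in THP-1 asked what macrophage-like differentiation changes in this line. Macrophage genes rose: the scavenger receptor CD163 by 7.86 ± 0.42, the complement gene C1QA by 8.65 ± 0.50, and the matrix protein SPP1 by 7.98 ± 0.20. So did the lipid receptor OLR1 by 7.72 ± 0.51 and the scavenger receptor COLEC12 by 7.64 ± 0.47. FABP4, a fatty acid carrier, was at least 599-fold higher (not called in DESeq2, adjusted p = 0.168), and FCGR3A, an Fc receptor with the near-identical copy FCGR3B, at least 181-fold. C1QC had 1813 counts against 2, a ratio of 879.9, 95% counting interval 243 to 7271. SLCO2B1, a transporter, rose by 9.15 ± 0.40 and GBP1, an interferon-induced GTPase, by 7.27 ± 0.47. Falls included the immediate early genes FOSB (-6.52 ± 0.50) and EGR1 (-4.21 ± 0.23), with WNT7B (-4.02 ± 0.37), the transcription factor DACH1 (-3.39 ± 0.18), NLRC3 (-2.99 ± 0.18), PPP1R27 (-2.67 ± 0.15), UNC5C (-2.64 ± 0.10) and SHISAL1 (-2.61 ± 0.25). CLK2 (-4.68 ± 1.34) and YTHDC1 (-3.08 ± 1.19), both of RNA splicing, fell in calls that rested on 1 library. Without replicate 1 of THP-1 DMSO they were at -1.57 (adjusted p = 0.488) and -0.15 (0.967), and without replicate 2 at -5.62 and -4.01. The call of YTHDC1 also ended without either PMA library (0.131 and 0.116). SPI1 rose by 0.48 ± 0.11 (adjusted p = 0.00233), and SMARCA4 and SMARCA2 fell (-0.46 ± 0.07 and -0.22 ± 0.06), the latter not without replicate 1 of THP-1 DMSO (adjusted p = 0.0677). Without replicate 1 or 2 of THP-1 DMSO C1QA was at 7.83 and 12.78 and COLEC12 at 9.68 and 6.70. OLR1 was at 8.43 without the former and CD163 at 8.76 without the latter, and FOSB was at -5.47 and -10.94 without replicate 1 or 2 of PMA. The fitted fold of C1QC was 12.85 and 8.53 without either DMSO library. Genes higher and lower numbered 3177 and 2880 (edgeR, Benjamini-Hochberg). With library size alone the share that were higher went from 52.5% to 41.0%, and with only the 4 libraries compared the counts were 1993 and 1023. The main fit gave each gene the same spread in all groups, though the PMA pair differed more than any other pair. Its PMA p-values and standard errors may thus be too small.

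By list, 29 of 30 macrophage markers rose with PMA and 1 fell (camera adjusted p = 5.9e-25), with the transmembrane gene GPNMB at 4.54 ± 0.11, CD14 at 6.11 ± 0.20 and CSF1R at 2.67 ± 0.11. All 27 interferon genes rose (5.0e-29), MX1, an antiviral GTPase, by 6.01 ± 0.15 and IFI6 by 5.20 ± 0.17. PU.1 target genes rose in 26 and fell in 3 of 35 (8.2e-12; 28 higher adjusted over the list alone), the oxidase subunit CYBB by 4.97 ± 0.14 and LYZ by 2.27 ± 0.07. Lysosomal genes rose in 21 of 24 (2.4e-19; PSAP 2.57 ± 0.06) and adhesion and matrix genes in 16 of 20 (6.9e-09; VCAN 3.42 ± 0.14). Targets of p53 rose in 11 with 2 lower of 22 (0.00211; 3 lower adjusted over the list alone; CDKN1A 2.51 ± 0.09). Falls prevailed in SWI/SNF subunits (14 lower and 1 higher of 27, 4.1e-05), cholesterol synthesis (14 lower of 19, 1.4e-07), the KMT2A fusion program (9 and 1 of 22, 1.2e-04; BCL2 -1.97 ± 0.07, MYC -0.92 ± 0.08) and blood transcription factors (13 and 8 of 28, 0.0139; MYB -1.19 ± 0.07). They prevailed in MYC and ribosome biogenesis (18 of 30, 8.1e-07), DNA replication (16 of 25, 2.3e-07) and mitosis (16 of 20, 2.3e-07). These 13 calls held with an estimated correlation, with the largest adjusted p at 0.0479.

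List calls with PMA that did not hold were those of inflammatory genes (13 of 22 higher, camera adjusted p = 2.3e-04; adjusted p = 0.174 with an estimated correlation) and MHC class II (3 of 6 higher, 0.0326; adjusted p = 0.0657 with an estimated correlation; HLA-DRA 3.28 ± 0.56). Nor did those of the integrated stress response (9 higher and 2 lower, 0.0106; adjusted p = 0.183 with an estimated correlation) and erythroid and megakaryocyte genes (4 of 6 lower, 0.0475, and 0.0659 with library size alone; adjusted p = 0.243 with an estimated correlation). Without replicate 1 of PMA, 8 inflammatory genes were called higher in place of 13, and 1 erythroid gene lower in place of 4. These settings were added after the data were seen. The lists without a call were granulocyte genes (8 higher and 5 lower, 0.0801; S100A8 3.83 ± 0.15), unfolded protein and heat shock genes (6 and 2, 0.0835), lymphoid genes (3 and 1, 0.0801) and epithelial and fibroblast genes (1 higher, 0.291; 0 adjusted over the list alone). With library size alone the granulocyte and lymphoid lists were called (0.0494 and 0.0482). Also without a call were the BCL2 family (3 and 5, 0.563), FLT3 and STAT5 output (4 and 6, 0.450) and ERK genes (8 and 6, 0.554). The PMA pair was the one whose counts differed most, with a chi-square per degree of freedom of 32.7.

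DB2313 in THP-1 asked what inhibition of PU.1 changes, in libraries that the labels place in no batch. The largest rises included GDF15, a stress cytokine, by 8.73 ± 0.49, the matrix protease MMP9 by 8.68 ± 0.29 and MDGA1, an adhesion gene, by 8.62 ± 0.28. ANKRD22, KRT80, CD22 and DDO went from 1 to 3 counts to 1072, 1866, 2506 and 824. The ratio was 798, 95% counting interval 221 to 6593 for the keratin KRT80 and 714, 95% counting interval 244 to 3466 for the lectin CD22, whose call was lost in DESeq2 (adjusted p = 0.0915). TDRD9, GGT5 and STAB1, without a count in DMSO, were at least 202-fold, 159-fold and 153-fold higher. RGS18, which regulates G protein signalling in blood cells, fell (-7.02 ± 0.24), as did WDR49 (-6.50 ± 0.31), the cortisol-producing enzyme HSD11B1 (-6.19 ± 0.31) and the phosphatase PTPRO (-5.88 ± 0.36). GABBR2 (-5.69 ± 0.37), TIFAB (-5.51 ± 0.44) and WNT7B (-5.50 ± 0.41) fell too. SERPINB10 (-8.47 ± 0.38) and SERPINB2 (-8.22 ± 0.22), protease inhibitors that overlap on 1 strand, also fell, and UGT3A2 had 2 counts against 791 (ratio 0.00216, 95% counting interval 2.6e-04 to 0.00784). SPI1 itself was at -0.17 ± 0.11 (adjusted p = 0.198). It was called lower without a count filter (-0.20, 0.0424) and with only the 4 libraries compared (-0.26, 0.0277). IRF8 fell (-2.93 ± 0.09), MYB (-3.45 ± 0.08), MYC (-1.82 ± 0.08) and LYZ (-5.00 ± 0.08). CD14 rose by 7.09 ± 0.20, ITGAM by 3.90 ± 0.10, CDKN1A by 3.68 ± 0.09 and CEBPA by 0.91 ± 0.10. Without replicate 1 or 2 of THP-1 DMSO the fitted folds of the low-count genes were 11.90 and 8.51 for ANKRD22, 12.70 and 8.37 for KRT80, 8.55 and 13.10 for CD22 and 8.42 and 11.51 for DDO, and without either DB2313 library -11.68 and -7.65 for UGT3A2. Without replicate 2 of THP-1 DMSO MMP9 was at 9.79, and without replicate 1 of DB2313 HSD11B1 was at -6.87 and PTPRO at -6.67. Genes higher and lower numbered 6028 and 4955, 65.4% of those tested, and the median of all genes was 0.14.

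By list, growth genes fell with DB2313, MYC and ribosome biogenesis in 28 of 30 (camera adjusted p = 7.3e-16, 0.0289 with an estimated correlation; SRM -2.45 ± 0.10). DNA replication genes fell in 24 of 25 (3.6e-13, 0.0289 with an estimated correlation; MCM3 -2.32 ± 0.06). Adhesion and matrix genes rose in 16 and fell in 1 of 20 (0.00213, 0.0289 with an estimated correlation). PU.1 target genes went both ways, 18 higher and 13 lower of 35 (0.241), with the leukocyte antigen CD53 at 3.29 ± 0.12 and IL1B at 4.89 ± 0.51. Interferon genes rose in 24 and fell in 3 of 27 (2.2e-06; adjusted p = 0.0851 with an estimated correlation), IFITM1 by 4.71 ± 0.21. Lysosomal genes rose in 18 and fell in 2 of 24 (1.6e-04; adjusted p = 0.102 with an estimated correlation; 3 lower adjusted over the list alone). Targets of p53 rose in 14 and fell in 4 (0.00449; adjusted p = 0.102 with an estimated correlation; BTG2 4.15 ± 0.17), and ERK genes rose in 15 and fell in 3 (0.00696; adjusted p = 0.198 with an estimated correlation; DUSP4 3.98 ± 0.14). Macrophage markers rose in 17 and fell in 6 of 30 (0.0357; adjusted p = 0.221 with an estimated correlation; 18 higher adjusted over the list alone). Erythroid and megakaryocyte genes, markers of another lineage, rose in 5 of 6 tested (camera adjusted p = 0.0480, 0.272 with an estimated correlation). The platelet integrin ITGA2B rose by 7.19 ± 0.22. With RLE factors (0.0511) or library size alone (0.0513) the list call ended. The list has 21 members, and those too low for the count filter were not tested. A gene could pass that filter through the DB2313 group alone.

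Falls prevailed without holding under an estimated correlation in mitosis (10 lower and 3 higher, camera adjusted p = 0.0230; adjusted p = 0.202 with an estimated correlation) and SWI/SNF subunits (14 and 5, 0.0283; adjusted p = 0.0851 with an estimated correlation; 15 lower adjusted over the list alone), and also in unfolded protein and heat shock genes (10 and 5, 0.0312; adjusted p = 0.335 with an estimated correlation). The lists without a call with DB2313 were the BCL2 family (9 higher and 2 lower, 0.0857; BCL2A1 7.36 ± 0.53, and 11.51 and 6.23 without replicate 1 or 2 of DMSO) and epithelial and fibroblast genes (4 higher, 0.0849; the keratin KRT8 4.62 ± 0.40, the collagen COL1A1 5.32 ± 0.37). No call was made for inflammatory genes (13 and 2, 0.103; CXCL8 -4.85 ± 0.41), MHC class II (3 lower, 0.108; 2 adjusted over the list alone), FLT3 and STAT5 output (8 and 4, 0.152; SOCS1 4.39 ± 0.20) and granulocyte genes (12 and 5, 0.241). Nor was one made for lymphoid genes (7 and 1, 0.241), the KMT2A fusion program (7 and 7, 0.286), the integrated stress response (9 and 5, 0.367), blood transcription factors (11 and 11, 0.616) and cholesterol synthesis (8 and 3, 0.616). Median, mean and test differed in sign for the last-named blood transcription factors and the KMT2A program here, and with PMA for the BCL2 family, unfolded protein and heat shock genes and ERK genes.

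**Figure D4:**
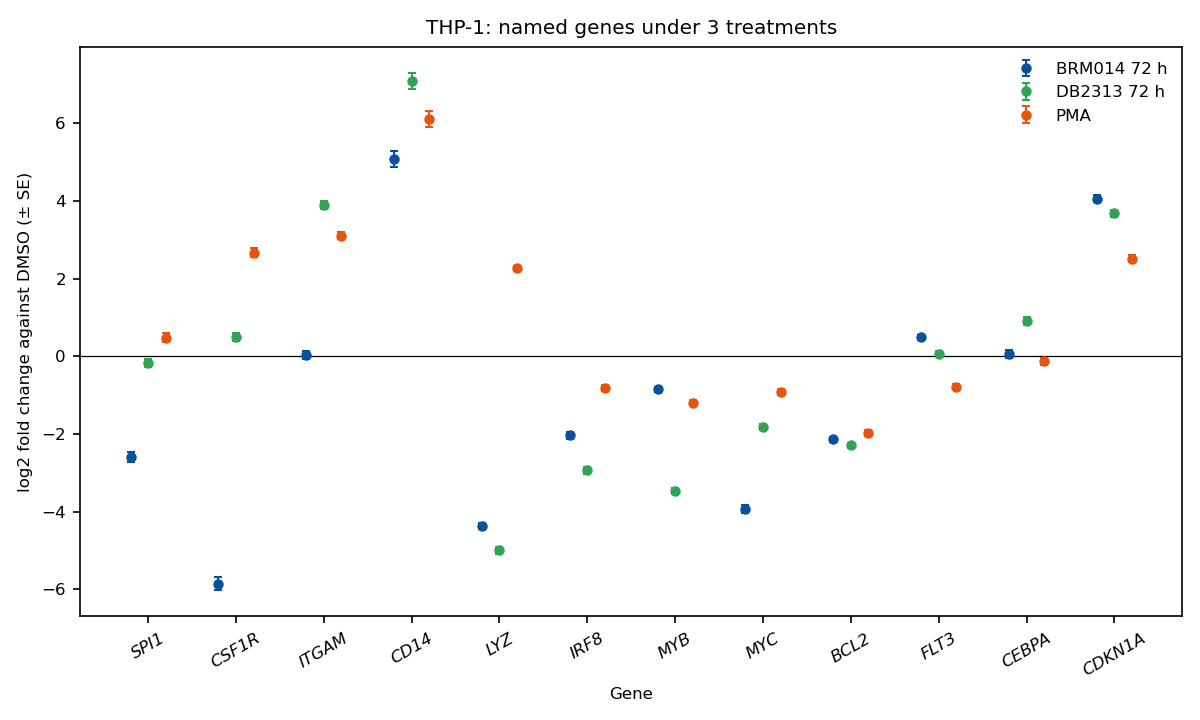
Log2 fold changes ± standard error of 12 genes in THP-1 under 72 h of BRM014, DB2313 and PMA, each against the same 2 DMSO libraries. SPI1 was at -2.59 with BRM014, -0.17 with DB2313 and 0.48 with PMA, and CSF1R at -5.85, 0.50 and 2.67.

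The labels do not say whether the BRM014 and DB2313 libraries were made together, so a batch cannot be told apart from the compounds. Set directly against DB2313 at the shared time of 72 h, with doses of 1 and 3 µM that differ, BRM014 left lower levels of PU.1 target genes. Of 35, 27 were lower and 4 higher (camera adjusted p = 6.1e-08, 0.0155 with an estimated correlation), among them CSF1R (-6.35 ± 0.17), ITGAX (-4.75 ± 0.17) and CD53 (-4.44 ± 0.13). SPI1 was at -2.42 ± 0.12. Cholesterol synthesis genes were lower in 15 of 19 (6.1e-08, 0.00122 with an estimated correlation; INSIG1 -3.10 ± 0.08). Interferon genes were lower in 24 and higher in 2 of 27 (3.4e-07; adjusted p = 0.0760 with an estimated correlation; MX1 -4.74 ± 0.17). Macrophage markers were lower and higher in 18 and 5 of 30 (0.00932; adjusted p = 0.164 with an estimated correlation; MMP9 -8.76 ± 0.29, GPNMB -4.78 ± 0.13). EGR1 (4.83 ± 0.19) and MYB (2.60 ± 0.08) were higher. Genes higher and lower with BRM014 than with DB2313 numbered 5101 and 5186. Against the shared DMSO libraries, the effects of 72 h BRM014 and DB2313 correlated at r = 0.414 across genes (0.519 in simulations of unchanged groups; covariance difference 1.05). They shared 3039 genes higher in both (1862 if independent), 2827 lower in both (1386) and 1536 opposite (3217). BRM014 at 72 h and PMA correlated at 0.216 (0.504 simulated; covariance difference 0.305), with 1573 higher in both (981), 1523 lower in both (806) and 1290 opposite (1778). That correlation was 0.132 without replicate 1 of PMA and 0.345 and 0.348 without replicate 1 or 2 of DMSO. DB2313 and PMA correlated at 0.360 (0.521; 0.659), with 2023, 1525 and 1200 (1140, 850 and 1971). At 24 h BRM014 correlated at 0.402 with DB2313 (0.534; 0.821) and 0.229 with PMA (0.522; 0.254), the latter 0.367 and 0.379 without replicate 1 or 2 of DMSO and 0.153 among genes with an average log2 CPM of at least 3. In the simulations at most 1 gene was called in the same direction in both comparisons of such a pair. Unchanged groups give few calls, so part of each overlap may still come from the shared controls. The simulated r comes from the shared DMSO libraries alone, so an observed r under it is no sign of unlike effects.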

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

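No test in this part was chosen after its result was seen, but each of the 3 patterns weighed was noticed in the data first.

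Sterol and interferon lists and many single genes answered BRM014 differently in MOLM-13, MV-4-11 and THP-1. By an F test of the difference (edgeR quasi-likelihood, Benjamini-Hochberg), 7300 genes differed between the lines at 24 h and 8881 at 72 h. Of these, 1365 and 1560 were called in opposite directions in 2 of the lines. At 24 h the largest and the smallest log2 fold change of the 3 lines lay 4.49 apart for LRG1, 4.44 for the sphingosine phosphate receptor S1PR3, 4.37 for the anticoagulant receptor THBD, 2.76 for the integrin ITGAM, 1.07 for the receptor kinase FLT3 and 0.88 for MYB. At 72 h they lay 8.11 apart for RGS16, a brake on G protein signalling, 5.12 for the antibacterial enzyme LYZ, 4.53 for the cell cycle inhibitor CDKN1A, 4.45 for the desaturase SCD and 1.02 for FLT3. The interferon response list differed between MOLM-13 and MV-4-11 at 72 h with a camera adjusted p of 3.2e-13 (adjusted p = 0.0140 with an estimated correlation). The lines differ in genotype and in much else that the labels do not give, and no cause of these differences was tested.

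Cholesterol synthesis genes were higher at 72 h than at 24 h of BRM014 in MV-4-11 and mostly lower in the other lines, which may reflect the line. A single library as the cause is excluded: without any 1 of the 4 MV-4-11 libraries at least 18 of the 19 genes stayed called higher. Scaling for library composition is excluded as well, since 19 stayed called higher with RLE factors and with library size alone. The line stays open as an untested explanation. The labels give no time for the DMSO libraries, so time in BRM014 cannot be told apart from time in culture.

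DB2313 gave more called genes than any other comparison with DMSO in the fit of all 22 libraries. Its lead over the mean of the lines at 72 h was narrow, with 10983 against 10962. A bias of gene length is excluded as the cause, since exon length accounted for 0.882% of the variance of the log2 fold changes among the 95.6% of tested genes with a known length. A library batch of the DB2313 samples and the treatment cannot be told apart, because every DB2313 library has the same treatment and the labels give no batch. Of the called genes, 88.7% lay on the same side of the other 3 treated THP-1 groups as of DMSO, which either of them could give.

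The 2 PMA libraries differed from each other more than any other pair of replicates, with a chi-square per degree of freedom of 32.7. Reads shared with a pseudogene or duplicate by name are excluded as the cause. Without genes that have such a named copy the value was 26.6, against 8.16 for the highest other pair. Near-identical copies with symbols of their own were kept, so reads shared between those are not excluded. A few genes taking most of the counts are excluded too, with 28.1 without the 100 most abundant genes, against 8.80. A difference in the strength of the PMA response or in handling stays open, and no biological explanation was tested.

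The number of called genes in the mean of the lines was set beside other splits of the same libraries at both times. Among 100 of the 108 splits of the 12 libraries into 2 of 4 within each line, only the real split (1) gave as many calls, 9795 at 24 h and 11285 at 72 h in fits of these 12 libraries. The highest other splits gave 7311 and 8804 calls, and the median other split gave 0. The high ones exchange the treated and DMSO libraries of a whole line, with 6776 calls or more at 24 h and 8580 or more at 72 h, which points to the structure of the samples. Splits that mix both kinds within a line gave up to 3565 and 5165 calls. They put treated and DMSO libraries in 1 group, which widens the spread within it and lowers the calls. The real split was therefore bound to rank high, and the test cannot exclude chance between cultures or a batch.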

How the results depend on the processing

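The counts of list members without 1 PMA library (inflammatory genes higher 8 and 16, against 13) were chosen only after the result was seen, and every other alternative before the data were examined. The numbers of called genes kept within 1.5 times under RLE factors, library size alone, DESeq2, no filter, the filter of 1 CPM and the replicate block (30 counts each). A 2-fold minimum lowered them by construction: higher and lower numbered 1231 and 1310 in the mean of the lines at 24 h, 2402 and 2020 at 72 h, 1320 and 1570 in MOLM-13, 1135 and 1491 in MV-4-11 and 1868 and 1466 in THP-1 at 24 h, 2679 and 2760, 2272 and 1946, and 2793 and 1935 at 72 h, 1221 and 1165, 1208 and 426, and 779 and 456 for 72 h against 24 h, 1362 and 693 for PMA, 3671 and 2069 for DB2313, and 2108 and 3003 for BRM014 against DB2313. With only the 4 libraries compared, PMA gave 1993 and 1023. Under the same restriction the other 22 counts kept within 1.5 times, so fewer libraries alone do not account for the drop. In the fit of all 22 libraries each gene had 1 spread for all groups, and the PMA pair differed most (chi-square per degree of freedom 32.7). The PMA p-values and standard errors of that fit may thus be too small. The cause of the drop was not tested. Without 1 library, 1750 (replicate 1 of the 24 h group) to 1983 genes were higher at 72 h than at 24 h in THP-1, against 2724. Of the named gene results, 1867 kept direction and call with RLE factors, 1849 with library size alone, 1849 in DESeq2 and 1860 with the block. Tests of line differences have no direction and were judged by call alone. Without 1 library most results kept both, but some calls ended and some signs changed. Reversals were of uncalled values, and the cause was not tested. With library size alone, log2 fold changes were 0.037 for SMARCA4, 0.021 for MYB and 0.021 for ITGAM in the mean at 24 h, 0.045 for ITGAM and 0.15 for HOXA9 in MOLM-13 at 72 h, 0.010 for INSIG1 in MV-4-11 at 72 h, and 0.019 for SMARCA2 and 0.0093 for MYC at 72 h against 24 h in THP-1, where SMARCA2 was at 0.0039 with RLE factors and 0.0039 in DESeq2. SMARCA2 in MOLM-13 at 72 h was at -0.032 with no filter and -0.016 with only the libraries compared. ITGAM in THP-1 at 72 h was at -0.0044 with 18 libraries, -0.018 with those of the line and -0.014 with those compared, and FLT3 with DB2313 at -0.017 with those compared. Without 1 library, ITGAM in the mean at 24 h ranged from -0.23 to 0.052, HOXA9 in MOLM-13 from -0.43 to 0.18 at 24 h and -0.33 to 0.28 at 72 h, CD14 in MV-4-11 at 24 h from -0.82 to 0.31, SMARCA2 in MOLM-13 at 72 h from -0.043 to 0.054, CEBPA and ITGAM in THP-1 at 72 h from -0.011 to 0.12 and -0.12 to 0.20, CD14 in MOLM-13 and MYC in THP-1 at 72 h against 24 h from -0.18 to 1.35 and -0.11 to 0.048, and CEBPA with PMA from -0.33 to 0.077. In lists, fry gave the opposite direction at 24 h for the BCL2 family (adjusted p = 0.0316), FLT3 and STAT5 output (0.133) and epithelial genes (0.367), at 72 h for macrophage markers (1.2e-06), granulocyte genes (0.0148) and FLT3 and STAT5 output (1.8e-04), and with DB2313 for granulocyte genes (0.698); it compares a list with no other genes. Granulocyte genes at 72 h reversed with library size alone (0.919). Library size alone also ended the calls of mitosis in MOLM-13 at 24 h (0.126), granulocyte genes there at 72 h (0.0750) and SWI/SNF, macrophage and inflammatory genes at 72 h against 24 h (0.0587, 0.0647 and 0.0647), and the block ended that of the integrated stress response in THP-1 (0.0534). Among genes with an average log2 CPM of at least 3 the correlation of 24 h BRM014 with PMA was lower, as given above. The correlations of BRM014 effects between lines and between times were higher there: 0.626, 0.560 and 0.534 between MOLM-13 and MV-4-11, MOLM-13 and THP-1, and MV-4-11 and THP-1 at 24 h, 0.632, 0.656 and 0.629 at 72 h, and 0.804, 0.797 and 0.877 between the times. Without 1 library the first 6 ranged over 0.387 to 0.409, 0.353 to 0.378, 0.290 to 0.323, 0.459 to 0.470, 0.462 to 0.486 and 0.404 to 0.427, the times over 0.693 to 0.782, 0.686 to 0.782 and 0.752 to 0.846, BRM014 and DB2313 over 0.336 to 0.509 at 24 h and 0.364 to 0.506 at 72 h, BRM014 and PMA over 0.156 to 0.379 and 0.132 to 0.348, and DB2313 and PMA over 0.253 to 0.476. Depth limits genes near the floor of 0.133 to 0.213 CPM per library. Leaving out 1 library widely moved the folds of several named genes with 1 to 3 counts in a group.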

Other observations

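The final form of both tests on PMA-raised genes, with its check of the higher share, and the genes named for the PMA pair were chosen only after the result was seen.

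Inflammatory genes had a median log2 difference of 0.85 between replicates 1 and 2 of PMA, with 18 of 22 higher in replicate 1. Interferon genes had 0.38, with 24 of 27 higher, and erythroid and megakaryocyte genes -0.65, with 0 of 6 higher. The medians of the other 21 lists lay between -0.27 and 0.16, and with 1 library on each side no difference was tested. The chemokine CXCL8 was higher by 1.15 on the log2 scale, the survival factor BIRC3 was at 6.74 and 0.572 CPM, and the chloride channel gene CLIC1 was at 22.8 and 2.17. GTPBP6 (1.43 and 34.8 CPM) and the RNA-degrading enzyme PARN (0.664 and 13.3) were lower in replicate 1, and the co-chaperone DNAJA3 (7.25 and 0.400) was higher.

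Genes of the PMA response in THP-1 were also changed by BRM014 in the other lines, in both directions. The hypothesis was that SWI/SNF inhibition lowers genes of macrophage-like differentiation in lines that received no PMA. In MOLM-13 at 24 h, 271 of 763 genes that PMA raised at least 2-fold fell with BRM014, which is 35.5%, against a median of 26.9% (95% range 24.0% to 29.9%) in 10000 random sets matched on expression. In MV-4-11, 251 of 766 fell, which is 32.8%, against 25.6% (22.6% to 28.5%). The share that rose was raised too, at 35.3% against 27.8% in MOLM-13 and 36.8% against 27.2% in MV-4-11. The prediction was made stricter after the first shares were seen, and as first written the lower share alone would have met it. Genes that respond to PMA may respond to many treatments, an alternative added after seeing the data and not tested, so these shares leave the hypothesis open.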
